A study of Mus musculus with 7 samples.

How the data were processed

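RNA was measured in 7 libraries of mouse bone marrow-derived macrophages: untreated (n = 2), IL-4 (n = 2), aN, that is macrophages that had met apoptotic neutrophils (n = 1), and aN+IL-4 (n = 2). Libraries were made from polyadenylated RNA with a strand-specific dUTP method, per the labels; the strand setting of the read counting is not given in the sources used here. The deposited table holds 1 signal value per gene and library for 46078 Ensembl mouse genes, and the authors call these values normalized counts. TopHat2, DESeq2 and the build GRCm38 are named per the submitters' processing notes, without versions or options. All values of each column were whole multiples of 1 step (100% of values, tolerance 1e-06 reads, largest distance 7.42e-10), so each column is a read count divided by 1 factor per library, and whole reads were recovered for the count-based tests. The value of 1 read lay between 0.907 and 1.17 normalised counts, and the recovered totals lay between 10169740 and 13558767 reads per library. No column of per-sample values was left out, 809 genes had no name in the table and 189 shared a name with another gene. Gene coordinates, strands and overlaps came from GENCODE vM21 (GRCm38), in which 45143 of the 46078 gene identifiers were found (98.0%). Of the 23 genes with the largest named changes, 7 overlap a gene on the opposite strand and 3 a gene on the same strand.

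Groups and replicate numbers were taken from the sample titles. The replicate numbers go with the submitters' sample series and may mark a batch, but the labels do not describe one or pair the libraries. The difference between replicates 2 and 1 correlated across genes at r = 0.315 between untreated and IL-4, 0.276 between untreated and aN+IL-4 and 0.253 between IL-4 and aN+IL-4. This hint of pairing comes from the data, so results are also given with the replicate number as a block where it changes a call. That reading was made after the calls of both fits had been seen. Differences were tested with limma 3.58.1 in R 4.3.3 (linear model over the 4 groups, empirical Bayes with an intensity trend) on log2 of the normalized count plus 1, for the 11834 genes with a mean of at least 10 normalized counts, which hold 99.9% of the reads. The fit leaves 3 residual degrees of freedom, with 3.78 prior degrees of freedom added. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 5 comparisons between groups were IL-4 against untreated, aN+IL-4 against untreated, aN+IL-4 against IL-4, aN against untreated and aN+IL-4 against aN, and the 6th contrast was the interaction of aN and IL-4. The aN group has 1 library, so its contrasts borrow the spread of the other groups. For genes with no read in a group, a bound was computed against a floor of 3 reads over the group, and with 1 to 3 reads a ratio with its 95% counting interval is given.

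Groups of genes were tested with 15 lists: alternative activation, growth and angiogenic factors, extracellular matrix, apoptotic cell recognition and uptake, LXR and lipid efflux, sterol biosynthesis, NF-kB and classical inflammatory response, type I interferon response, cell cycle, lysosome, glycolysis, fatty acid oxidation, MHC class II presentation, immediate early and heat shock, and mitochondrially encoded transcripts. Another 10 sets held markers of macrophages, neutrophils, dendritic cells, T cells, B cells, fibroblasts or stroma, mast cells or basophils, eosinophils, erythroid cells, and megakaryocytes or platelets. Of their 436 genes 433 were in the table. The 18 sets with at least 3 tested members were tested with camera of limma at a preset correlation between genes of 0.01. Adjustment ran over the sets within each contrast, and the test was repeated with a correlation estimated per set. The repeated test has only the 3 residual degrees of freedom of the fit, so few lists can pass it. In IL-4 against untreated the fatty acid oxidation list had an estimated correlation of -0.0476, under the preset 0.01. Its unadjusted camera p still went from 0.000145 to 0.0264. A call lost with an estimated correlation therefore does not by itself show that list members move together. Over the 18 sets the estimates ran from -0.0503 for LXR genes to 0.888 for fibroblast or stromal markers. They were 0.886 for interferon, 0.781 for cell cycle, 0.58 for lysosome and 0.516 for glycolysis genes. Alternative activation had 0.209 and sterol genes 0.146. Where the estimate lies far over the preset 0.01, the camera p-values at the preset can be too small. Members called are counted over all tested genes and, separately, with p-values adjusted over the list alone. Named genes followed a fixed rule: among called genes without overlap between the libraries of the groups and with a mean of at least 50 normalized counts in the higher group, the 8 largest rises and 8 largest falls, without unnamed gene models, plus up to 4 members per list with the smallest p-values. For aN+IL-4 against aN the rule took 4 rises and 4 falls, and for the interaction 6 and 6. Some genes that the rule names are not reported here.

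As alternatives the tests were repeated with pseudocounts of 0.5 and 5, without a filter on low values, with a filter at a mean of 50, with TMM scaling, with only the groups compared in the fit, with the replicate number as a block and without each library in turn. They were also repeated on the recovered reads with edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0. For IL-4 against untreated limma called 1550 genes, edgeR 1544 and DESeq2 1549; for aN+IL-4 against untreated they called 1732, 1700 and 1670, and for aN+IL-4 against aN 774, 781 and 1003. For aN+IL-4 against IL-4 they called 0, 0 and 1, for aN against untreated 0, 0 and 4, and for the interaction of aN and IL-4 0, 0 and 1. The overlap of calls between the comparisons that share the untreated libraries was set against 20 simulated data sets without an effect. The tests were tested on simulated data with 200 changed genes among 11834: limma found 89% of 2-fold and 100% of 4-fold changes for IL-4 against untreated with 20 false calls, 90% and 100% with 16 false calls for aN+IL-4 against IL-4, and 72% and 98% with 17 false calls for aN against untreated. At most 200 calls could be true in each simulation. The false limma calls were therefore a larger share of all calls than the adjusted p threshold set above. The share of false calls among the observed calls was not measured. A simulated shift of 1 list was found in each of these designs (adjusted p at most 7.16e-21), with 0 of 17 other lists called. Genes were simulated without correlation, whereas the estimated correlation reached 0.886 for the interferon list. The simulation therefore does not measure false list calls in the observed libraries. With the same changes edgeR found 70% and DESeq2 73% of 2-fold changes for aN against untreated. The simulated counts varied independently, had no effect of replicate number and were changed only in genes with a reference mean of at least 50. Observed libraries of the same number deviate together, so these shares set no expectation for them. A count of 0 calls in a comparison therefore does not exclude changes of these sizes. Figures and coordinates were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Raw reads were not analysed here, and differences in splicing or transcript isoforms were not analysed here.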

Results

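Macrophages were grown for 7 days from the bone marrow of C57BL/6 mice aged 8 weeks, in medium conditioned by L929 cells, a source of the growth factor CSF1. Polyadenylated RNA was sequenced from 7 libraries in 4 groups, each collected after 24 h of culture. The untreated group (2 libraries) stayed in growth medium. The IL-4 group (2 libraries) also received 10 ng/ml of interleukin-4, a cytokine of type-2 immunity that signals through STAT6. The aN group (1 library) met apoptotic neutrophils for 30 min before washing. The aN+IL-4 group (2 libraries) met the neutrophils in the same way and was then given IL-4. Read totals of replicates 1 and 2 were 10169740 and 10793736 in untreated, 12030038 and 12077926 in IL-4, and 11665072 and 11153195 in aN+IL-4. The aN library had 13558767 reads. Between 16958 and 17620 genes had at least 1 read, and a floor of 3 reads corresponded to between 2.72 and 3.51 normalised read counts.

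Group values are mean normalised read counts ± SD over the 2 libraries of a group (n = 2), and differences are on the log2 scale from 1 fit over all 7 libraries. The aN group has no SD. Across genes, which are not independent replicates, the libraries of a group correlated at r = 0.989 (untreated), 0.983 (IL-4) and 0.99 (aN+IL-4). The labels do not say whether the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries. Intervals and floors cover counting error only. The gene lists, the comparisons and the rule for naming genes were fixed before the data were examined.

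The comparison of IL-4 against untreated macrophages asked which genes respond to the cytokine alone. Arg1 (ENSMUSG00000019987; chromosome 10, 24915221 to 24927484, minus strand, GRCm38) encodes the arginine-degrading enzyme arginase. It rose from 85.3 ± 39.6 to 65166 ± 3723 (log2 difference 9.64, adjusted p = 2.48e-05). The C-type lectin gene Mgl2 (ENSMUSG00000040950; chromosome 11, 70130329 to 70137550, plus strand) rose from 3.81 ± 2.09 to 3836 ± 1864 (log2 difference 9.62, adjusted p = 5.51e-05). Cdh1, which encodes E-cadherin, rose from 29.7 ± 6.02 to 3256 ± 303 (log2 difference 6.74, adjusted p = 2.48e-05). Flt1, which encodes a VEGF receptor, rose from 66.0 ± 12.5 to 4755 ± 609.8 (log2 difference 6.16, adjusted p = 2.48e-05). The homeobox gene Msx3 had 1 read in the untreated libraries together and 908 ± 287 normalised counts with IL-4. This is a ratio of 1624 with a counting interval of 291 to 64177 (adjusted p = 5.43e-05). Retnla, which encodes the secreted protein RELM-alpha, also had 1 read in the untreated libraries and reached 62.1 and 719 in the IL-4 libraries. Its ratio was 721 (counting interval 129 to 28495, adjusted p = 0.00913).

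A further 3 of the largest rises were in genes without any read in the untreated libraries. Against a floor of 3 reads over the group, the ribonuclease gene Rnase2a was at least 376-fold higher (adjusted p = 0.000261). Pdcd1lg2, which encodes the inhibitory ligand PD-L2, was at least 111-fold higher (adjusted p = 0.000311), and the potassium channel gene Kcnd3 at least 81.5-fold (adjusted p = 5.98e-05). The largest falls were led by Cx3cr1 (ENSMUSG00000052336; chromosome 9, 119901616 to 120069879, minus strand), which encodes the fractalkine receptor. Cx3cr1 fell from 10199.8 ± 258 to 718 ± 72.3 (log2 difference -3.83, adjusted p = 5.12e-05). Its annotated span overlaps 6 genes on the opposite strand and 3 on its own. The actin-regulating gene Marcksl1 fell from 956 ± 56.8 to 106 ± 23.0 (log2 difference -3.18, adjusted p = 0.000701). Falls were also seen for the integrin gene Itga8 (log2 difference -3.80) and the chemokine genes Cxcl10 (-3.55) and Cxcl2 (-2.99). The Fc receptor-like gene Fcrl1 (-3.37), the synuclein-interacting gene Sncaip (-3.25) and the sialyltransferase gene St3gal6 (-3.04) fell as well.

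Over the alternative settings the adjusted p ranged from 0.000126 to 0.0893 for Retnla, from 1.04e-05 to 0.0659 for Itga8 and from 6.23e-06 to 0.0869 for Cxcl10. It ranged from 0.000119 to 0.177 for Sncaip and from 8.56e-05 to 0.0693 for Cxcl2. Arg1, Mgl2, Cdh1, Flt1, Msx3, Rnase2a, Pdcd1lg2, Kcnd3, Cx3cr1, Marcksl1, Fcrl1 and St3gal6 stayed called in every setting run.

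**Figure D1:**
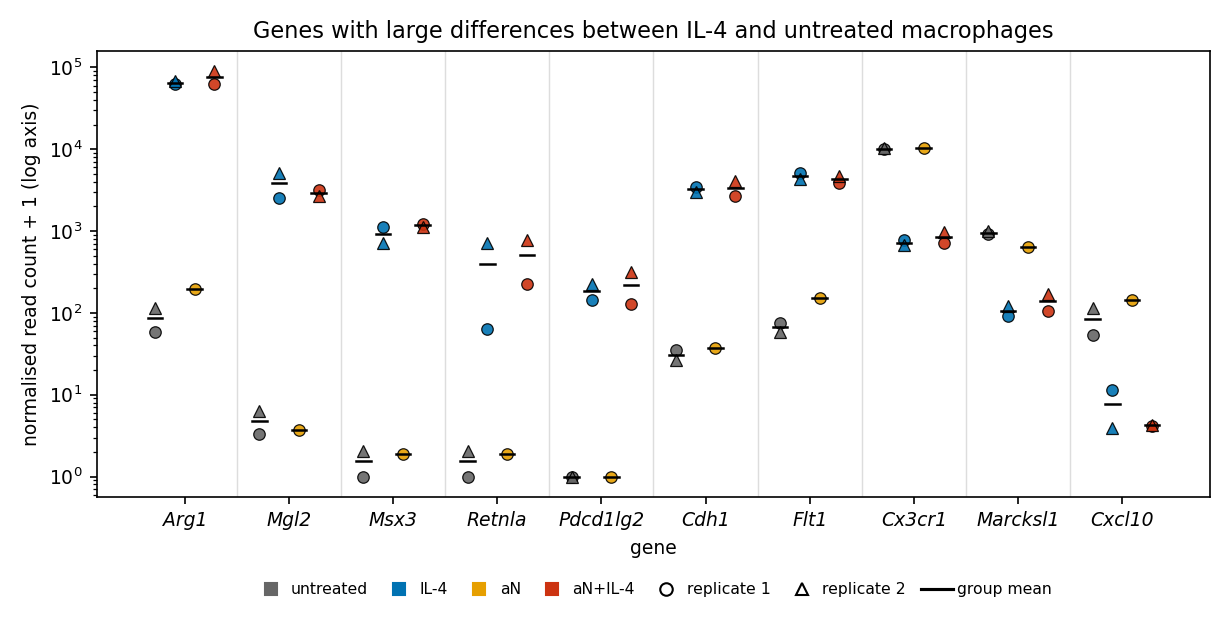
Normalised read counts plus 1 on a log axis for 10 genes, 1 point per library (circles, replicate 1; triangles, replicate 2), with the group mean as a bar. Arg1 lay at 57.3 and 113 in untreated, 192 in aN and between 62534 and 90362 in the 4 libraries with IL-4.

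Of 27 tested genes on the alternative activation list, which holds known targets of IL-4 and STAT6, 24 rose with IL-4 and 0 fell (26 and 1 when adjusted over the list alone). The median log2 difference was 4.70, or 4.77 with the 4 members at 3 reads or fewer set to the floor. The list passed the camera test (adjusted p = 6.28e-23). It did not pass with a correlation estimated from the data, a test with 3 degrees of freedom (adjusted p = 0.237 with an estimated correlation). Besides Arg1, Flt1 and Cdh1, the transcription factor gene Klf4 rose from 81.1 ± 0.573 to 890.3 ± 98.1 (adjusted p = 2.48e-05).

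Among 22 genes of sterol biosynthesis, 0 rose and 7 fell (0 and 12 when adjusted over the list alone). The list was lower at a median of -0.43 (adjusted p = 4.04e-05, and adjusted p = 0.545 with an estimated correlation). The sterol desaturase gene Sc5d fell from 447 ± 7.76 to 235 ± 33.8. The sterol synthesis gene Hsd17b7 (log2 difference -0.70) and the sterol transport gene Stard4 (-0.77) fell too. Of 18 glycolysis genes 0 rose and 5 fell (1 and 9 when adjusted over the list alone). Pdk1, a kinase gene whose product inhibits pyruvate dehydrogenase, fell from 1549.7 ± 45.5 to 882 ± 75.3. The enzyme genes Pfkl (-0.68) and Tpi1 (-0.66) and the lactate transporter gene Slc16a3 (-1.03) were among the other falls. The glycolysis list was lower at a median of -0.30 (adjusted p = 0.00672, and adjusted p = 0.70 with an estimated correlation). Without untreated replicate 1 it was not called (adjusted p = 0.0912, in a range of 4.74e-05 to 0.70 over all alternatives).

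Of 17 fatty acid oxidation genes 3 rose and 0 fell (9 and 0 when adjusted over the list alone). They were the enzyme gene Echs1, from 613 ± 29.1 to 1123 ± 127, the electron carrier gene Etfa (log2 difference 0.43) and the thiolase gene Acaa2 (0.42). The list was higher at a median of 0.30 (adjusted p = 0.000652, and adjusted p = 0.237 with an estimated correlation). All 26 cell cycle genes had a negative difference (median -0.41), and 1 of them, the thymidylate synthase gene Tyms, fell (1 also when adjusted over the list alone). The cell cycle list was lower (adjusted p = 9.86e-07, and adjusted p = 0.70 with an estimated correlation).

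In the list of 20 NF-kB and classical inflammatory genes, 5 rose and 8 fell with IL-4 (5 and 9 when adjusted over the list alone). The list as a whole was not called (adjusted p = 0.125). The pattern receptor gene Tlr2 fell from 1773 ± 229 to 312 ± 47.9 and the cytokine gene Tnf from 407 ± 38.9 to 104 ± 8.00. The cytokine gene Tnfsf9 also fell (log2 difference -1.92), whereas the chemokine gene Ccl7 rose from 617 ± 197 to 10156 ± 3580.2. Growth and angiogenic factor genes gave 6 rises and 1 fall among 18 (9 and 3 when adjusted over the list alone, list adjusted p = 0.054). Hbegf, an EGF receptor ligand gene, rose from 4.98 ± 0.434 to 625 ± 204, and Igf1 rose by 0.91 on the log2 scale. The platelet-derived growth factor gene Pdgfb fell from 1799.5 ± 357 to 668 ± 12.4. Of 27 matrix genes 4 rose and 3 fell (5 and 4 when adjusted over the list alone, list adjusted p = 0.676). The metalloproteinase genes Mmp12 (3780.1 ± 26.7 to 16457 ± 6802) and Mmp13 (278 ± 141 to 3143 ± 1102) rose. The collagen gene Col18a1 (-0.69) and the protease gene Plau (-0.73) fell.

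Of 24 genes for the recognition and uptake of apoptotic cells 4 rose and 2 fell (5 and 3 when adjusted over the list alone, list adjusted p = 0.676). The integrin gene Itgb3 rose from 76.0 ± 13.2 to 1698 ± 207, the scavenger receptor gene Cd36 rose by 1.56 and the engulfment gene Elmo1 fell by 0.67 on the log2 scale. The LXR and lipid efflux list had 1 rise and 3 falls among 14 (1 and 4 when adjusted over the list alone, list adjusted p = 0.601). The rise was that of the sterol exporter gene Abcg1 (281 ± 41.8 to 1368 ± 414), and the falls were those of Abca1, Mylip and Apoe. The median and the mean differed in sign for the matrix (-0.022 and 0.080), uptake (-0.20 and 0.062) and LXR (-0.070 and 0.067) lists, and the test pointed up for the matrix list and down for the others. Of 25 lysosome genes 6 rose and 0 fell (7 and 0 when adjusted over the list alone, list adjusted p = 0.141). They were led by the proton pump gene Atp6v0d2 (419 ± 42.0 to 5205 ± 495), with the cathepsin genes Ctsl and Ctsk and the cholesterol transport gene Npc1. Immediate early and heat shock genes had 4 rises and 0 falls among 15 (5 and 1 when adjusted over the list alone, list adjusted p = 0.0645). The transcription factor gene Atf3 rose from 1213 ± 44.1 to 2939 ± 207. None of 8 mitochondrially encoded transcripts passed (list adjusted p = 0.778, mt-Nd1 log2 difference 0.12).

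The type I interferon list gave opposite values in the IL-4 libraries. Its median log2 difference from untreated was 1.32 in IL-4 replicate 1 and -1.02 in IL-4 replicate 2. Of its 27 genes 1 fell, Cxcl10, and 0 rose (the same counts when adjusted over the list alone, list adjusted p = 0.676). Without IL-4 replicate 2 the list was higher than in untreated macrophages (adjusted p = 9.17e-12), and without IL-4 replicate 1 it was lower (adjusted p = 3.21e-07, in a range of 9.17e-12 to 0.921 over all alternatives). Irf7, a transcription factor gene of the interferon response, stood at 1256 in IL-4 replicate 1 and 200.2 in IL-4 replicate 2. In the untreated libraries it stood at 210.5 and 159. MHC class II genes had a median difference of 1.97, with 1 of 9 called (2 when adjusted over the list alone, list adjusted p = 0.054). That gene, H2-DMa, rose by 0.90 on the log2 scale. With the replicate number as a block the list was called (adjusted p = 0.00108), as were Cd74 (0.000563), H2-Eb1 (0.0016) and H2-Aa (0.0052). The invariant chain gene Cd74 stood at 90.0 and 269.8 untreated and at 518 and 2057 with IL-4 (adjusted p = 0.0549). Libraries numbered 2 held more MHC class II RNA than those numbered 1, at list medians of 0.71 and -0.71 in untreated and 3.01 and 0.93 in IL-4.

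In all, 1550 of 11834 tested genes passed for IL-4 against untreated (limma, Benjamini-Hochberg), 887 higher and 663 lower, of which 364 and 238 differed at least 2-fold. The differences computed within replicate numbers 1 and 2, a possible batch that the labels do not describe, correlated at r = 0.786 across all tested genes. The count was 567 without untreated replicate 1, 584 without untreated replicate 2, 793 with no filter on low values and 2366 with the replicate block. Lists not called with all libraries were called without some of them (adjusted p in parentheses here and for libraries left out of later comparisons). Without IL-4 replicate 1 these were MHC class II (0.00131) and immediate early genes (0.0153), higher, and macrophage markers (0.00263) and NF-kB genes (0.0326), lower. Without IL-4 replicate 2 they were growth factors (0.00677) and lysosome genes (0.00172), higher, and fibroblast markers (0.0195), lower. Without untreated replicate 1 neutrophil (0.0108) and fibroblast markers (0.0495) were lower and growth factors higher (0.0474), and without untreated replicate 2 MHC class II genes were higher (0.00756) and macrophage markers lower (0.0486). Without either aN+IL-4 library the growth factor, MHC class II, immediate early and macrophage lists were called, at an adjusted p between 0.0471 and 0.0485. The replicate block called macrophage (0.0316) and fibroblast markers (0.0458), both lower. The edgeR test called growth factors (0.0357), lysosome (0.00927) and immediate early genes (0.0361) higher, and NF-kB genes (0.0361) and macrophage markers (0.00136) lower.

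Among the list members and markers named for IL-4, some calls were lost in at least 1 alternative setting. They were those of Abca1, Acaa2, Apoe, Cd5, Col18a1, Ctsk, Ctsl, Etfa, H2-DMa, Hsd17b7, Igf1, Mmp12, Mmp13, Mylip, Npc1, Pfkl, Plau, Sc5d, Siglecf, Slc16a3, Stard4, Tpi1 and Tyms.

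The comparison of aN+IL-4 against untreated macrophages asked what both stimuli do together. Arg1 rose to 76763 ± 19233 (log2 difference 9.86, adjusted p = 2.99e-05) and Mgl2 to 2927 ± 311 (9.32, 5.75e-05). Cdh1 rose to 3382 ± 958 (6.77, 2.99e-05) and Flt1 to 4287 ± 549 (6.01, 2.99e-05). Fn1 (ENSMUSG00000026193; chromosome 1, 71585520 to 71653200, minus strand), which encodes the matrix protein fibronectin, rose from 1326 ± 605 to 26156 ± 13971 (log2 difference 4.27, adjusted p = 0.00182). The ribonuclease gene Ear2 (ENSMUSG00000072596; chromosome 14, 44102654 to 44103534, plus strand) rose from 2.65 ± 3.74 to 386 ± 247 (log2 difference 7.10, adjusted p = 0.00474). Ear2 and Rnase2a belong to a family of close paralogs whose reads can be shared. Msx3 and Retnla stood at 2114 and 894 times their single untreated read (counting intervals 379 to 83540 and 160.1 to 35357). Rnase2a, Pdcd1lg2 and Kcnd3 were at least 498-fold, 131-fold and 103-fold higher.

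Among the falls in aN+IL-4 against untreated, the iron exporter gene Slc40a1 fell from 802 ± 76.1 to 101 ± 93.4. The chemokine receptor gene Cxcr3 fell from 83.7 ± 12.2 to 9.58 ± 4.28. Cx3cr1 (log2 difference -3.60), Cxcl10 (-4.23), Sncaip (-3.94), Fcrl1 (-3.38) and Cxcl2 (-3.32) fell as in IL-4 alone. Across the alternative settings the adjusted p ranged from 5.69e-05 to 0.0678 for Retnla, from 4.04e-06 to 0.0617 for Ear2 and from 4.34e-07 to 0.0609 for Cxcl10. It ranged from 2.76e-05 to 0.118 for Sncaip and from 0.00111 to 0.114 for Slc40a1.

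The alternative activation list held 24 rises and 1 fall among 27 in aN+IL-4 (26 and 1 when adjusted over the list alone), at a median of 4.53, also with 4 members set to the floor. It was called (adjusted p = 9.04e-23, and adjusted p = 0.258 with an estimated correlation). The fall was that of Il4ra, a receptor chain for IL-4, named after its values were seen. Sterol genes had 0 rises and 8 falls among 22 (1 and 11 when adjusted over the list alone), with the enzyme genes Sc5d and Sqle among the falls. The list was lower (adjusted p = 0.000339, and adjusted p = 0.716 with an estimated correlation). Glycolysis genes had 0 rises and 8 falls among 18 (0 and 10 when adjusted over the list alone), with Slc16a3 falling from 2125 ± 636 to 851 ± 37.3. This list was also lower (adjusted p = 0.000339, and adjusted p = 0.722 with an estimated correlation). Fatty acid oxidation genes had 3 rises and 0 falls among 17 (10 and 0 when adjusted over the list alone), with Echs1 at 1169 ± 3.21. That list was higher (adjusted p = 0.000738, and adjusted p = 0.258 with an estimated correlation).

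The cell cycle list was lower, with 2 falls among 26 and 1 when adjusted over the list alone (adjusted p = 1.76e-06, and adjusted p = 0.722 with an estimated correlation). The interferon list was lower at a median of -1.01, with 2 falls among 27, Cxcl10 and the GTPase gene Gbp3, and the same number when adjusted over the list alone. Its adjusted p was 0.0039 (adjusted p = 0.78 with an estimated correlation). MHC class II genes were called higher at adjusted p = 0.0493, with 1 rise among 9 and 2 rises and 1 fall when adjusted over the list alone (adjusted p = 0.722 with an estimated correlation). The call was lost without untreated replicate 1 (0.121), without aN+IL-4 replicate 2 (0.25), with TMM scaling (0.0501) and with edgeR (0.0627), in a range of 0.00105 to 0.722 over all alternatives. Neutrophil markers rose in 8 of 13 genes (9 rises and 1 fall when adjusted over the list alone), and the list was higher (adjusted p = 0.000738, and adjusted p = 0.722 with an estimated correlation). S100a8 (ENSMUSG00000056054; chromosome 3, 90668978 to 90670035, plus strand), a calprotectin subunit gene, rose from 148 ± 117 to 1110.0 ± 304. S100a9, the gene of the other subunit, rose from 232 ± 231 to 1676 ± 455 and the granule peptide gene Camp from 8.05 ± 8.07 to 127 ± 7.12. These 3 calls were lost in some alternative settings (adjusted p from 0.000333 to 0.135, 0.00168 to 0.193 and 0.00382 to 0.167), and that of Gbp3 as well (0.00192 to 0.17).

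The remaining lists were not called in aN+IL-4 against untreated (adjusted p = 0.0534 or more). Growth factor genes had 5 rises and 2 falls among 18 (8 and 3 when adjusted over the list alone), matrix genes 5 and 3 among 27 (6 and 5) and uptake genes 5 and 2 among 24 (5 and 3). LXR genes had 2 rises and 4 falls among 14 (4 and 4 when adjusted over the list alone), NF-kB genes 4 and 8 among 20 (5 and 10) and lysosome genes 5 and 0 among 25 (7 and 0). Immediate early and heat shock genes had 5 and 0 among 15 (5 and 1), and mitochondrially encoded transcripts 0 and 0 among 8. Median and mean differed in sign for the uptake (-0.22 and 0.024), LXR (-0.0041 and 0.16) and lysosome (-0.075 and 0.27) lists, with the test down, down and up. Hbegf rose to 584 ± 246, Itgb3 to 1763 ± 13.4 and Ctsk from 29.2 ± 9.91 to 147 ± 17.6.

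The test called 1732 of 11834 genes (limma) for aN+IL-4 against untreated, 984 higher and 748 lower, with 397 and 263 at least 2-fold different. The differences within replicate numbers 1 and 2 correlated at r = 0.849 across all tested genes. The count was 579 without untreated replicate 1, 653 without untreated replicate 2, 814 without aN+IL-4 replicate 1 and 485 without aN+IL-4 replicate 2. It was 826 with no filter on low values. The immediate early list was called higher without either IL-4 library (0.047 and 0.0476), untreated replicate 1 (0.0459) or aN+IL-4 replicate 1 (0.00376). NF-kB genes were lower without either IL-4 library (0.0263 and 0.025) or aN+IL-4 replicate 2 (0.0294), macrophage markers without either IL-4 library (0.0334 and 0.0346) or aN+IL-4 replicate 1 (0.0456), and mitochondrially encoded transcripts higher without untreated replicate 1 (0.0206). The replicate block also called immediate early genes (0.045) and macrophage markers (0.0353). So did edgeR (0.0375 and 0.00254), which called NF-kB genes lower as well (0.0242).

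The calls of Ctsk, Sc5d, Slc16a3 and Sqle were lost in at least 1 of the alternative settings. Of the genes called in both comparisons with untreated, 790 were higher and 549 lower in both, and 0 moved in opposite directions. Independent lists of these sizes would share 73.8 and 41.9 genes. Libraries simulated without any effect of treatment shared 0 calls over 20 draws, which sets no expectation because a simulation without effects leaves hardly any gene to call. The log2 differences of both comparisons had r = 0.923 and a covariance of 0.458 across genes, against r = 0.504 and a covariance of 0.0273 in the simulated libraries, where the shared controls alone correlate them. The 2 untreated libraries were not split between the comparisons, so part of the excess over independent lists may come from the shared controls.

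The comparison of aN+IL-4 against IL-4 addressed the question in the study's title, what apoptotic cells add to macrophages that receive IL-4. Of the 27 alternative activation genes 0 were called, and Arg1 stood at 65166 ± 3723 in IL-4 and 76763 ± 19233 in aN+IL-4. Chil3 (ENSMUSG00000040809; chromosome 3, 106147554 to 106167564, minus strand), a chitinase-like gene with a close paralog in Chil4, stood at 4973 and 4035 in the IL-4 libraries. In the aN+IL-4 libraries it stood at 10672 and 25280.0 (log2 difference 1.87). Ear2 stood at 92.1 ± 61.8 in IL-4 and 386 ± 247 in aN+IL-4 (log2 difference 2.07). Among matrix genes Fn1 stood at 5938 ± 1227 and 26156 ± 13971 (2.04), and the coagulation factor gene F13a1 at 482 ± 283 and 1273 ± 357 (1.51). Col18a1 stood at 290.3 ± 18.1 and 185 ± 18.7 (-0.65). None of these differences passed the limma test (adjusted p = 1 when rounded) or limma with the replicate block, and edgeR with the replicate block, added after the data were seen, called Ear2 (adjusted p = 0.0431). In the matrix list 1 gene was higher and 1 lower when adjusted over the list alone, while the list as a whole was not called (adjusted p = 0.655).

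**Figure D2:**
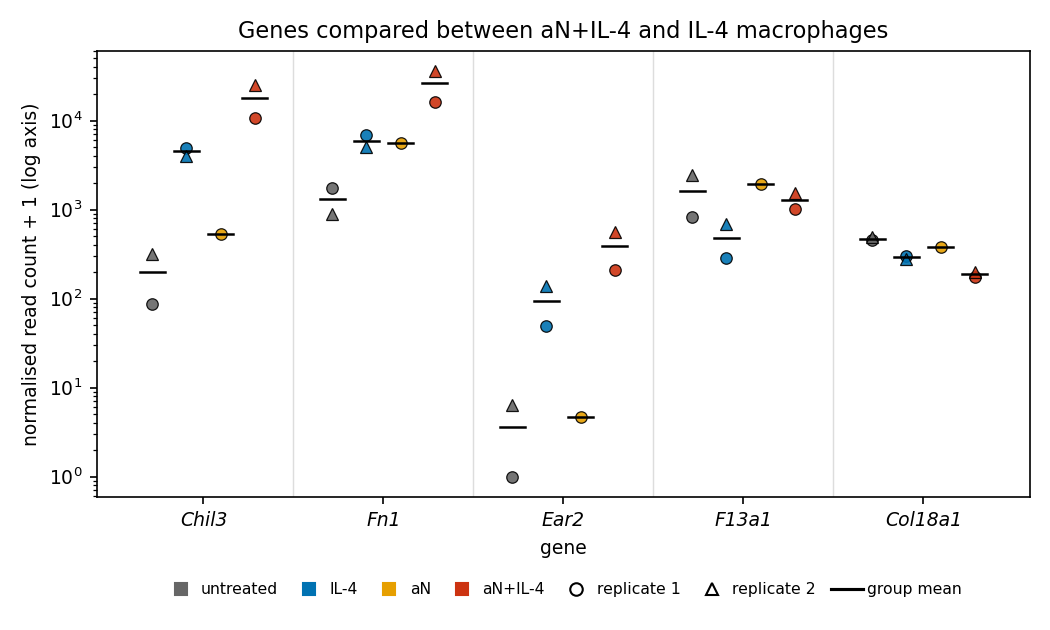
Normalised read counts plus 1 on a log axis for Chil3, Fn1, Ear2, F13a1 and Col18a1, 1 point per library (circles, replicate 1; triangles, replicate 2), with the group mean as a bar. Fn1 stood at 6806 and 5071 in the IL-4 libraries, at 5570.4 in the aN library and at 16278 and 36035 in the aN+IL-4 libraries.

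Neutrophil markers were higher in aN+IL-4 than in IL-4 as a list, at a median log2 difference of 3.28 (camera adjusted p = 6.49e-18, and adjusted p = 0.548 with an estimated correlation). Over all genes 0 of 13 were called, and 9 were higher when adjusted over the list alone. With the replicate block S100a8, Ngp, Lcn2 and Ltf were called (adjusted p = 0.0447 for each, against 1 when rounded without it). S100a8 stood at 120.1 ± 64.2 in IL-4 and 1110.0 ± 304 in aN+IL-4. The granule protein gene Ngp stood at 84.0 ± 57.8 and 1100.1 ± 209, the lipocalin gene Lcn2 at 23.5 ± 21.4 and 330.4 ± 52.9, and Camp at 2.48 ± 3.50 and 127 ± 7.12. All 19 markers in the table together took 0.0424% (exact 95% interval 0.0413 to 0.0436) and 0.0572% (0.0558 to 0.0587) of all reads in the aN+IL-4 libraries and 0.0518% (0.0506 to 0.053) in the aN library. They took 0.00846% (0.00795 to 0.009) and 0.0134% (0.0127 to 0.014) in the IL-4 libraries, and 0.0102% (0.00959 to 0.0108) and 0.0188% (0.018 to 0.0196) in the untreated libraries. Of the 13 tested markers, which no other list holds, 10 had a mean of at least 10 normalised counts in the libraries without neutrophils, such as the receptor gene Trem1 at 396 ± 144 and the enzyme gene Padi4 at 108 ± 6.04 in the untreated group.

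**Figure D3:**
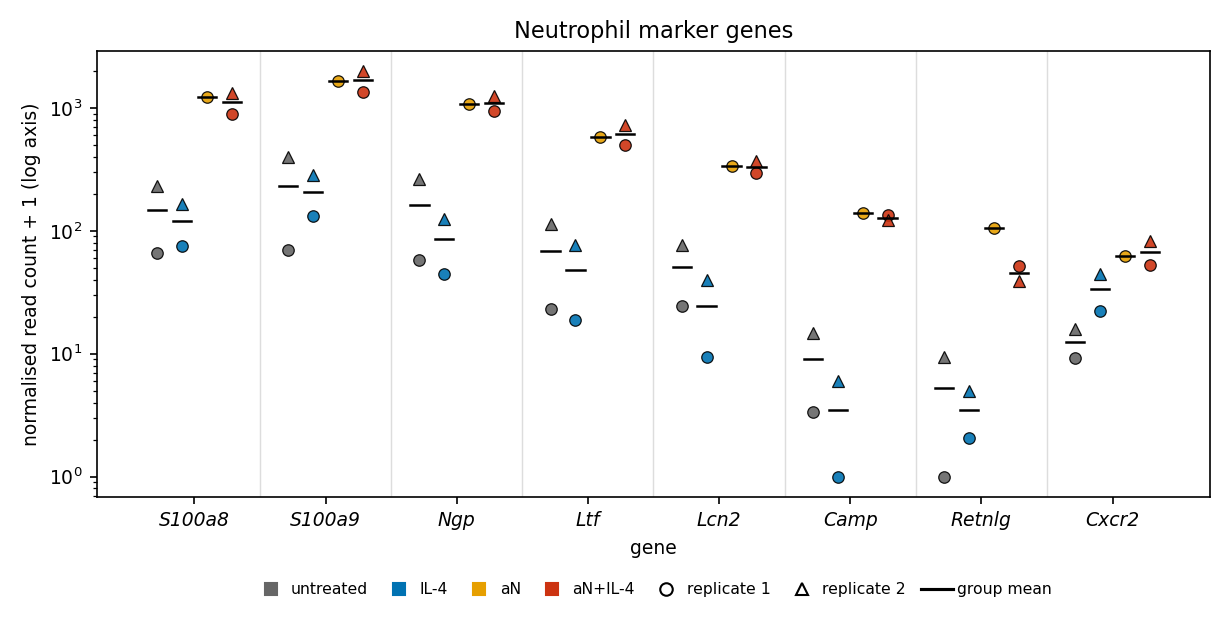
Normalised read counts plus 1 on a log axis for 8 neutrophil marker genes, 1 point per library (circles, replicate 1; triangles, replicate 2), with the group mean as a bar. S100a8 lay between 65.5 and 231 in the 4 libraries without neutrophils and between 895 and 1325 in the 3 libraries with neutrophils.

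The interferon list was lower in aN+IL-4 than in IL-4, with 27 of 27 differences negative and a median of -1.05 (camera adjusted p = 5.09e-16, and adjusted p = 0.987 with an estimated correlation). Without IL-4 replicate 1 it was not called (adjusted p = 0.901, in a range of 3.49e-57 to 0.987 over all alternatives). Irf7 stood at 1256 and 200.2 in the IL-4 libraries and at 122 and 183 in aN+IL-4. Glycolysis genes were also lower, with 16 of 18 differences negative and a median of -0.093 (adjusted p = 0.00899, and adjusted p = 0.987 with an estimated correlation). That call was lost without IL-4 replicate 1 (0.144) and without aN+IL-4 replicate 2 (0.0831), in a range of 0.00117 to 0.987 over all alternatives.

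The other 15 lists were not called in aN+IL-4 against IL-4 (adjusted p = 0.0916 or more), with 0 members called over all genes in any of them. Alternative activation had adjusted p = 0.365 and uptake genes 0.969. Alternative activation and matrix genes were called higher without IL-4 replicate 2 (0.0106 and 0.0472) and without aN+IL-4 replicate 1 (0.00861 and 0.00975), in ranges up to 0.987 over all alternatives. The MHC class II list was lower without IL-4 replicate 1 (0.0103) or aN+IL-4 replicate 2 (0.00658), and higher without IL-4 replicate 2 (0.035) or aN+IL-4 replicate 1 (0.0182). Cell cycle genes were lower without IL-4 replicate 1 (7.87e-14) and higher without IL-4 replicate 2 (1.62e-09). Lysosome genes were higher without IL-4 replicate 1 (0.0162) and lower without IL-4 replicate 2 (1.08e-06) or aN+IL-4 replicate 1 (0.00975). Uptake genes and macrophage markers were higher without IL-4 replicate 1 (0.00464 and 0.00116) and lower without IL-4 replicate 2 (0.0106 and 0.0475). Immediate early genes were higher without aN+IL-4 replicate 1 (0.00975) and lower without aN+IL-4 replicate 2 (0.00656). Without IL-4 replicate 2 growth factors were lower (0.0114) and fibroblast markers higher (0.0106), and mitochondrially encoded transcripts were higher without IL-4 replicate 1 (1.12e-05) or aN+IL-4 replicate 2 (0.0319). The replicate block called lysosome genes lower (0.00745) and mitochondrially encoded transcripts higher (0.00397).

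Over all genes the limma test called 0 of 11834 for aN+IL-4 against IL-4 (lowest adjusted p = 0.851). An unadjusted limma p under 0.05 was reached by 230 genes, where 592 would be expected by chance. Why fewer p-values were small than expected by chance was not tested. The 0 calls of the limma test do not show that differences were absent. The edgeR test called 0 and DESeq2 called 1, and with the replicate block limma called 5 and edgeR 7. The DESeq2 gene, named after its values were seen, was Cd177, which encodes a neutrophil surface protein. Cd177 stood at 3.16 and 3.97 in the IL-4 libraries and 85.1 and 124 in aN+IL-4. Without IL-4 replicate 2 the limma test called 61 genes, 2 higher and 59 lower, of which 19 were on the interferon list and 2 on the neutrophil list.

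The comparison of aN against untreated macrophages asked what apoptotic neutrophils do without IL-4. It rests on 1 aN library that is assumed to vary like the libraries of the other groups. Genes of the interferon list stood higher in the aN library, with 27 of 27 differences positive and a median of 1.69 (camera adjusted p = 7.94e-17, and adjusted p = 0.631 with an estimated correlation). Irf7 was at 1425 against 185 ± 36.6 in untreated, the protease gene Usp18 at 451 against 81.3 ± 9.20, and the antiviral gene Ifit2 at 754 against 221 and 323. The neutrophil list was higher as well, at a median of 3.11 and with 9 of 13 genes higher when adjusted over the list alone (adjusted p = 3.62e-11, and adjusted p = 0.631 with an estimated correlation). S100a8 was at 1231 against 148 ± 117. Lysosome genes were higher (23 of 25 positive, median 0.21, adjusted p = 1.41e-05) and cell cycle genes lower (24 of 26 negative, median -0.32, adjusted p = 2.15e-10). For both it was adjusted p = 0.631 with an estimated correlation. Immediate early and heat shock genes were higher (12 of 15 positive, adjusted p = 0.0236) and fibroblast or stromal markers lower (4 of 4 negative, adjusted p = 0.0283). These lists also had adjusted p = 0.631 with an estimated correlation. The immediate early call was lost without untreated replicate 2 (0.0686), as was the fibroblast call (0.284), with ranges of 2.02e-05 to 0.631 and 0.00137 to 0.631 over all alternatives.

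Alternative activation genes were not called as a list in aN against untreated (adjusted p = 0.0612, in a range of 1.35e-06 to 0.631 over all alternatives), with 2 higher when adjusted over the list alone. Flt1 stood at 149.7 against 66.0 ± 12.5, and Klf4 at 122 against 81.1 ± 0.573. Fn1 stood at 5570.4 against 1326 ± 605 and the metalloproteinase gene Mmp9 at 161 against 26.8 ± 11.5. Nr1h3, which encodes the receptor LXR-alpha, was at 188 against 116 ± 12.2 and Abcg1 at 453 against 281 ± 41.8. The uptake (0.0612), sterol (0.0656), LXR (0.0659), macrophage marker (0.0659) and matrix (0.0943) lists were not called, nor were the remaining 6 (adjusted p = 0.272 or more). Over all alternatives the ranges were 2.92e-05 to 0.631 for matrix genes, 0.00454 to 0.631 for LXR genes and 3.53e-05 to 0.985 for MHC class II genes. The replicate block called alternative activation (1.35e-06), matrix (2.92e-05), LXR (0.00454) and MHC class II genes (3.53e-05) higher, and fibroblast markers were not called with it (0.111). The edgeR test called alternative activation (0.0299), matrix (0.0293), LXR (0.0293) and uptake genes (0.0385) and macrophage markers (0.0494) higher. Without untreated replicate 2 alternative activation (0.00339) and matrix genes (0.00428) were higher, and without untreated replicate 1 uptake (0.011), glycolysis (0.000366) and mitochondrially encoded genes (0.00424) were higher and sterol genes lower (0.000516). Without either IL-4 library the uptake, LXR and macrophage marker lists were higher (0.0237 to 0.0422).

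No single gene passed, since limma called 0 of 11834 genes (lowest adjusted p = 0.815), with 386 at an unadjusted p under 0.05. The edgeR test also called 0, and DESeq2 called 4, which are named after their values were seen. They were Cd177 (log2 difference 4.57, DESeq2 adjusted p = 0.000157), the membrane protein gene Flrt2 (1.21, 0.000254), Retnlg, a gene expressed in neutrophils (4.58, 0.0335), and Flt1 (1.18, 0.0374). Without IL-4 replicate 1 limma called 23 genes, all higher in aN and 9 of them on the interferon list, and without IL-4 replicate 2 it called 27, all higher and 11 on that list.

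The comparison of aN+IL-4 against aN macrophages asked what IL-4 does in macrophages that met apoptotic neutrophils. The aN group has 1 library, so the gene and list calls of this comparison take the spread of the other groups for it. Arg1 rose from 192 to 76763 ± 19233 (log2 difference 8.61, adjusted p = 0.000226). Mgl2 was at 1077 times its 3 reads in aN (counting interval 368 to 5224) and Msx3 at 1294 times its single read (232 to 51149). Rnase2a, with no read in aN, was at least 305-fold higher. The largest falls were of interferon genes, which were high in that 1 library (list median 1.69 over untreated) and also in IL-4 replicate 1 (1.32), which met no neutrophils. Except for Cxcl10, these falls therefore cannot be assigned to IL-4. Cxcl10 was lower with IL-4 alone as well, at 10.5 and 2.97 in the IL-4 libraries against 52.6 and 115 in the untreated libraries. The interferon-induced gene Ifit3 fell from 561 to 11.3 ± 1.06 (adjusted p = 0.036), and Ifit3b, its paralog, had no read in aN+IL-4 and was at least 65.5-fold lower (0.031). The surface protein gene Ly6a fell from 378 to 11.4 ± 8.64 (0.0384) and Cxcl10 from 142 to 3.21 ± 0.0879 (0.0117). In the alternative settings the adjusted p ranged from 0.000185 to 0.161 for Ifit3, from 0.00218 to 0.171 for Ly6a, from 2.07e-07 to 0.0675 for Cxcl10 and from 0.00113 to 0.138 for Ifit3b.

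The interferon list held 4 falls among 27 in aN+IL-4 against aN (26 when adjusted over the list alone) and was lower at a median of -3 (adjusted p = 1.6e-12, and adjusted p = 0.683 with an estimated correlation). The alternative activation list held 22 rises and 0 falls (24 and 1 when adjusted over the list alone), at a median of 4.59, also with the 6 members at 3 reads or fewer set to the floor. It was called (adjusted p = 4.02e-26, and adjusted p = 0.308 with an estimated correlation). Macrophage markers were lower as a list, with 1 rise and 4 falls among 14 and 2 and 6 when adjusted over the list alone (adjusted p = 0.0117, and adjusted p = 0.796 with an estimated correlation). Cx3cr1 fell by 3.60 on the log2 scale, the LPS co-receptor gene Cd14 fell by 2.39 and the Fc receptor gene Fcgr3 rose by 0.91. The pore protein gene Mpeg1 fell from 49405 to 14924 ± 1909, a call lost in some alternative settings (adjusted p from 9.83e-08 to 0.118). Glycolysis genes were lower, with 0 rises and 6 falls among 18 and 9 falls when adjusted over the list alone (adjusted p = 4.83e-06, and adjusted p = 0.683 with an estimated correlation). Sterol genes were lower, with 1 rise and 4 falls among 22 and the same when adjusted over the list alone (adjusted p = 0.00605, and adjusted p = 0.683 with an estimated correlation). Fatty acid oxidation genes were higher, with 2 rises among 17 and 3 when adjusted over the list alone (adjusted p = 0.00407, and adjusted p = 0.337 with an estimated correlation).

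The other lists were not called in aN+IL-4 against aN (adjusted p = 0.0611 or more). Growth factors had 1 rise and 1 fall (5 and 2 when adjusted over the list alone), matrix genes 2 and 3 (4 and 3), uptake genes 2 and 1 (2 and 2) and LXR genes 1 and 3 (2 and 4). NF-kB genes had 4 rises and 5 falls (4 and 9 when adjusted over the list alone), lysosome genes 2 and 1 (2 and 2) and immediate early genes 2 and 0 (3 and 2). Among them Tlr2 (-2.12), Tnf (-1.70) and Pdgfb (-1.83) fell, and Hbegf rose by 6.91 on the log2 scale. Neutrophil markers did not pass in any of 13 genes (list adjusted p = 0.644), with S100a8 at 1231 in aN and 1110.0 ± 304 in aN+IL-4. MHC class II genes were called higher without any single untreated or IL-4 library and without aN+IL-4 replicate 1 (0.00875 to 0.0338), and NF-kB genes lower without either IL-4 library (0.0376 and 0.0349), without aN+IL-4 replicate 2 (0.0454) or with edgeR (0.0257). Without aN+IL-4 replicate 1 cell cycle genes were lower and immediate early genes higher (0.0369 each). The replicate block called neutrophil markers lower and mitochondrially encoded transcripts higher (0.0245 each). The limma test called 774 of 11834 genes, 461 higher and 313 lower, with 281 and 160 at least 2-fold different. The count was 204 without aN+IL-4 replicate 2, 324 without aN+IL-4 replicate 1, 469 without untreated replicate 1 and 473 without untreated replicate 2. It was 1361 without IL-4 replicate 1 (671 higher and 690 lower) and 1364 without IL-4 replicate 2 (669 higher and 695 lower). With no filter on low values 912 genes were called for aN+IL-4 against aN, 311 higher and 601 lower, so the majority direction turned in these 3 settings.

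The interaction of aN and IL-4 asked whether the effect of IL-4 differed with and without apoptotic neutrophils, and rests on the same single aN library. The interferon list had a lower IL-4 effect with neutrophils, with 27 of 27 values negative, 16 of them lower when adjusted over the list alone, and a median of -2.94 (camera adjusted p = 1.12e-25, and adjusted p = 0.82 with an estimated correlation). Interaction values were -4.70 for Irf7, -3.27 for Usp18 and -5.11 for Ifit3. Cell cycle genes had a higher value (25 of 26 positive, median 0.32, adjusted p = 6.59e-07) and lysosome genes a lower one (23 of 25 negative, median -0.24, adjusted p = 4.4e-06). Both had adjusted p = 0.82 with an estimated correlation. Among lysosome genes Atp6v0d2 stood at -0.57 and Ctsl at -0.70. Glycolysis (lower, adjusted p = 0.0203), fibroblast or stromal markers (higher, 0.0224) and sterol biosynthesis (higher, 0.0434) were also called, again with adjusted p = 0.82 with an estimated correlation. These 3 calls were lost without untreated replicate 2 (0.55, 0.163 and 0.497) and without aN+IL-4 replicate 2 (0.0561, 0.0836 and 0.0561). The fibroblast call was also lost without IL-4 replicate 1 (0.126), and the sterol call without IL-4 replicate 2 (0.275), without aN+IL-4 replicate 1 (0.0747) and with edgeR (0.0554). Ranges over all alternatives were 9.97e-06 to 0.82 (glycolysis), 0.0015 to 0.82 (fibroblast) and 0.000553 to 0.82 (sterol).

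Alternative activation genes were not called as a list in the interaction (adjusted p = 0.512, in a range of 0.00769 to 0.923 over all alternatives), with 2 lower when adjusted over the list alone. Flt1 had an interaction value of -1.33 and Klf4 of -0.77. The list was called lower without IL-4 replicate 1 (0.0122) and without aN+IL-4 replicate 2 (0.0466), as were matrix (0.0148 and 0.0156) and immediate early genes (0.0057 and 8.23e-05). The replicate block called the same 3 lists lower (0.00769, 0.00367 and 0.000545), MHC class II genes lower (0.00044) and mitochondrially encoded transcripts higher (0.00447). Uptake genes were lower without untreated replicate 1 (0.0299), IL-4 replicate 2 (0.00319) or aN+IL-4 replicate 1 (0.0384), and growth factors (0.0408) and macrophage markers (0.0281) without IL-4 replicate 2. Without IL-4 replicate 1 MHC class II genes were lower (0.0313) and mitochondrially encoded transcripts higher (0.0122), the latter also without untreated replicate 2 (0.0245). Neutrophil markers were higher without untreated replicate 1 (0.0113) and lower without untreated replicate 2 (0.0117).

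Over all genes limma called 0 of 11834 (lowest adjusted p = 0.994), with 350 at an unadjusted p under 0.05. The edgeR test called 0 and DESeq2 called 1, Ms4a4c, a membrane protein gene named after its values were seen (log2 value -3.64, DESeq2 adjusted p = 0.00118). Without IL-4 replicate 2 the interaction test called 110 genes, 3 higher and 107 lower, 23 of them on the interferon list.

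**Figure D4:**
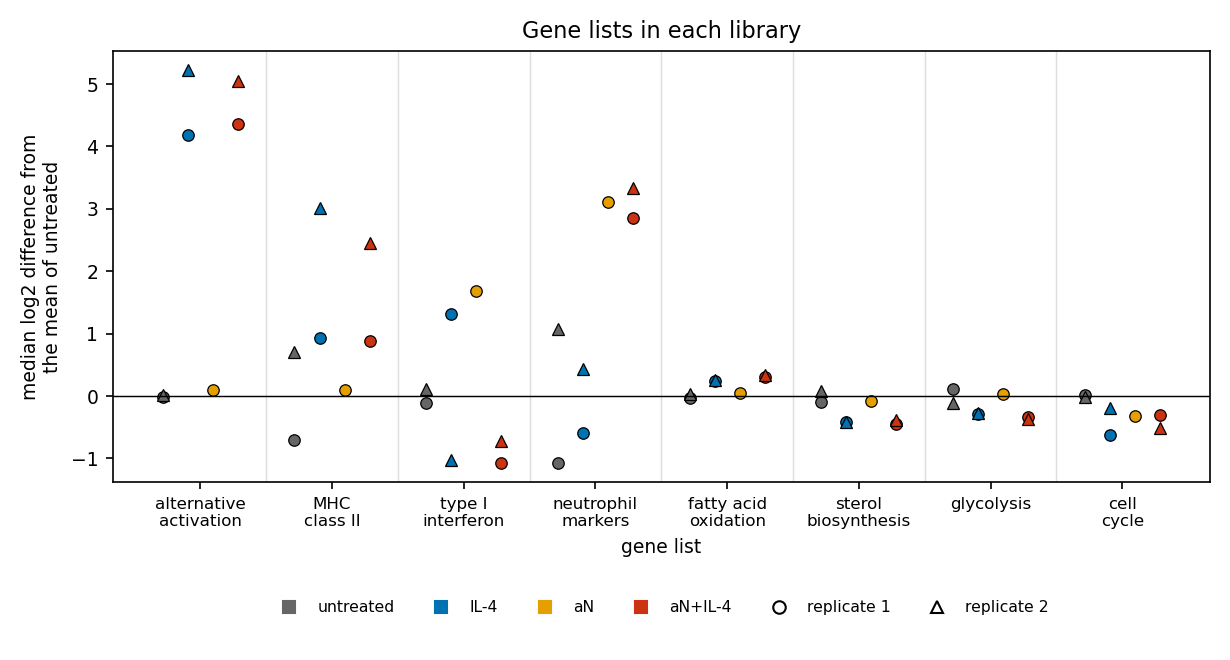
Median log2 difference from the mean of the untreated libraries for 8 gene lists, 1 point per library. The interferon list stood at 1.32 in IL-4 replicate 1 and 1.69 in aN but between -1.07 and -0.71 in IL-4 replicate 2 and aN+IL-4, and the alternative activation list between 4.18 and 5.22 in the 4 libraries with IL-4 and at 0.10 in aN.

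Marker lists of other cell types tested whether cells other than macrophages contributed RNA. Macrophage markers gave 3 rises and 4 falls among 14 in IL-4 against untreated (3 and 6 when adjusted over the list alone, list adjusted p = 0.054). Cd14 fell from 4449 ± 597 to 877 ± 106 and Fcgr3 rose from 4298 ± 112 to 8444 ± 481. In aN+IL-4 against untreated the counts were also 3 and 4 (4 and 6 when adjusted over the list alone, list adjusted p = 0.0552). Neutrophil markers did not pass in IL-4 against untreated (0 of 13, list adjusted p = 0.621), while the replicate block called Cxcr2 higher (0.00972) and Trem1 lower (0.00983). Nor did fibroblast or stromal markers (0 of 4, list adjusted p = 0.169), with the collagen gene Col3a1 at 29.9 ± 17.5 and 9.54 ± 7.54. Of 2 tested T cell markers, Cd5 fell from 28.4 ± 2.79 to 3.10 ± 1.57 with IL-4 and Cd4 was not called. Of 2 tested megakaryocyte or platelet markers, Vwf, which encodes von Willebrand factor, rose from 397 ± 10.5 to 1052 ± 186 and Pf4 was not called (log2 difference -0.10). Of 2 tested eosinophil markers, Siglecf rose from 6.63 ± 1.10 to 18.9 ± 1.52 and Ccr3 was not called (2 higher when adjusted over the list alone). The single tested dendritic cell marker, Zbtb46, stood at 0 and 5.29 in untreated, 5.26 and 30.7 in IL-4, 1.81 in aN, and 10.5 and 17.5 in aN+IL-4. Its differences from untreated were not called (log2 difference 2.49 with IL-4, adjusted p = 0.18, and 2.54 with aN+IL-4, adjusted p = 0.165), but were called with the replicate block (0.0321 and 0.0286, the lowest over the alternatives, in ranges up to 0.564 and 0.536). The single tested B cell marker, Cd79b, was not called in any comparison or alternative, except in aN+IL-4 against untreated with the replicate block (0.0497). That block also called Ccr3 higher (0.0126) and Col3a1 lower (0.0234) in IL-4 against untreated. No mast cell or basophil marker and no erythroid marker passed the filter on low values.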

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

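The tests of gene lists below were planned, and the 9 tests of explanations were chosen only after the results were seen. Some of the tests of explanations could not decide their question whatever the values, for lack of a second aN library or of a library of neutrophils alone.

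A test of the difference between the effects of IL-4 with and without apoptotic neutrophils (the interaction, camera adjusted p) passed its threshold for 6 lists: type I interferon response (1.12e-25), cell cycle (6.59e-07), lysosome (4.4e-06), glycolysis (0.0203), fibroblast or stromal markers (0.0224) and sterol biosynthesis (0.0434). A difference is not established for any of them: the aN group has 1 library, the adjusted p was 0.82 for each with an estimated correlation, and no single gene passed (lowest limma adjusted p = 0.994, with 350 genes at an unadjusted p under 0.05, 0 called by edgeR and 1 by DESeq2). The interferon, cell cycle and lysosome calls held in every library left out in turn, except aN replicate 1, which this contrast needs. Lysosome genes stood highest in the same libraries as interferon genes, at medians over untreated of 0.185 in IL-4 replicate 1 and 0.21 in aN replicate 1, against -0.0662 in IL-4 replicate 2 and 0.02 and -0.153 in aN+IL-4. The glycolysis, fibroblast and sterol calls were lost without untreated replicate 2 (0.55, 0.163 and 0.497), among other libraries.

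Interferon-response genes were high in IL-4 replicate 1 and aN replicate 1 (medians 1.32 and 1.69 over untreated on the log2 scale) and not in IL-4 replicate 2 (-1.02) or aN+IL-4 (-1.07 and -0.71), which is what the interferon difference between groups rests on. An exchange of labels between IL-4 replicate 1 and aN replicate 1 is excluded, since alternative activation genes stood higher in IL-4 replicate 1 by a median of 3.42 (quartiles 2.18 and 5.08). A batch shared by all libraries numbered 1 is excluded as the whole cause, since interferon genes were not higher in replicate 1 than 2 in untreated and aN+IL-4 (larger of the median differences -0.18). A response of macrophages to apoptotic neutrophils stays open for aN replicate 1 (median 1.69), because that group has 1 library and IL-4 replicate 1, which met no neutrophils, reached similar values. No biological explanation was tested for IL-4 replicate 1.

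Neutrophil transcripts were higher in the 3 libraries that had met apoptotic neutrophils. RNA of the added neutrophils may be their source: the summed increase was alike with and without IL-4 (ratio 1.01, range 0.701 to 1.38 over the libraries). Granulocyte precursors of the primary granule stage are argued against as the source of this increase. Mpo, Elane, Prtn3 and Ctsg had a median shift of -0.378 (range -1.49 to 0.418, positive for Elane). This compares with 3.20 to 4.99 for S100a9, S100a8, Ngp, Lcn2, Ltf and Camp. The primary granule genes had low counts, with Mpo at most at 50.8, in untreated replicate 2, and Ctsg at 0.907 in aN. Precursors present alike in all libraries are not addressed by this test. Later precursors, which carry the genes that were higher, were not tested. Synthesis by the macrophages themselves cannot be told apart from added RNA, because Ly6g, with 33 reads in the 3 libraries (8 to 15 in each) and 0 in the other 4, was not measured in a library of neutrophils alone.

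Chil3, Fn1 and Ear2 stood higher in both aN+IL-4 libraries than in both IL-4 libraries, without passing the test. Whether RNA of the added neutrophils is the whole cause cannot be decided, because the increase without IL-4 rests on 1 aN library. With that library the increases were larger with IL-4 than without, while neutrophil markers increased alike (ratio 1.01, at most 1.38). The lowest ratios the libraries allow were 12.9 for Chil3, 2.03 for Fn1 and 20.7 for Ear2. These ratios leave out counting error. For Ear2 the increase without IL-4 was 0.983 normalised counts, where 1 read in aN was 0.907. Spread between replicate libraries stays open as well: the lowest adjusted p over the alternatives had a median of 0.378 over the 3 genes (0.66 for Chil3, 0.378 for Fn1 and 0.0431 for Ear2). An effect of both stimuli beyond that of each alone depends on the scale: those increases exceeded a sum of the single effects in counts, but on the log2 scale the median interaction was 0.196 (range -0.1055 to 1.185), which cannot be told apart from a product of the single effects with 1 aN library.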

How the results depend on the processing

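Alternatives chosen after the data were seen were edgeR with replicate block, both high-interferon libraries (IL-4 replicate 1 and aN replicate 1) left out together, single libraries left out of the list tests, and the gene families below; the others were planned. IL-4 against untreated called 1550 genes, 793 with no filter on low values (22080 genes tested), 2366 with the replicate block and 567 to 1757 when single libraries were left out. aN+IL-4 against untreated called 1732, 826 with no filter and 485 to 2476 when libraries were left out. aN+IL-4 against IL-4 called 0, 1 with DESeq2, 5 with the replicate block, 7 with edgeR and replicate block, and 0 to 61 when libraries were left out. The 5 were S100a8, Ngp, Lcn2, Ltf and Cd177, and edgeR with the replicate block added Ear2 and F7. aN against untreated called 0, 4 with DESeq2 and 0 to 27 when libraries were left out; aN+IL-4 against aN called 774 and 204 to 1364; the interaction called 0, 1 with DESeq2 and 0 to 110. In aN+IL-4 against aN the share of calls that were higher was 59.6%, and 34.1% of 912 calls with no filter on low values. Libraries left out leave some groups with a lone sample, which is assumed to vary like the other groups. The number of lists called was 5, 8, 3, 6, 6 and 6 in the 6 contrasts in that order, and 0 in each with an estimated correlation. The replicate block gave 8 lists for IL-4 against untreated, 5 for aN+IL-4 against IL-4 and 11 for the interaction. List calls that it changed are given in the report, and it changed no other list call. The edgeR test gave 10 for IL-4 against untreated and 11 for aN against untreated. With single libraries left out the lists called were 5 to 10, 8 to 11, 3 to 12, 6 to 10, 7 to 9 and 5 to 10, and with both high-interferon libraries out 10 for IL-4 against untreated and 7 for aN+IL-4 against IL-4. For named genes no direction was reversed where the main fit or the alternative called the gene. Without a call in either, the sign changed in 17, 7, 52, 22, 12 and 28 settings of single genes. Calls were lost in 115, 132, 0, 0, 129 and 0 settings of single genes and gained in 31, 39, 12, 8, 28 and 6. TMM scaling moved the median of all genes by at most 0.0051 on the log2 scale. The cause was not tested. With no filter the adjustment runs over more genes of low value, and depth limits calls among genes near the floor of 3 reads.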

Other observations

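The gene families here were chosen after the data were seen. They were drawn by patterns in gene symbols, which need not follow function. Mgl2, described above as a C-type lectin gene, was not counted among the C-type lectin and Siglec genes. Of 26 tested cytokine receptor genes 11 rose and 2 fell with IL-4 against untreated: Il1rl2 rose by 4.4 on the log2 scale (adjusted p = 0.000112), Il1rl1, which encodes the IL-33 receptor, by 3.23 (0.011), Il1rap by 2.13 (0.00143) and Csf2rb by 1.66 (0.000271), while Il13ra1 fell by 2.24 (0.00335) and Il10ra fell by 0.76 (0.00435). In aN+IL-4 against untreated 11 rose and 4 fell, with Il12rb2 (-1.20) and Il4ra (-0.54) also called as falls. Both already stood lower with IL-4 alone, without a call. Il12rb2 had means of 120 in untreated, 73.0 in IL-4 and 51.8 in aN+IL-4, and Il4ra of 2027, 1442 and 1389. Of 25 chemokine and chemokine receptor genes 6 rose and 6 fell with IL-4: Ccl7 (4.03), Ccl12 (2.44), Ccl2 (2.16) and Ccl6 (1.69) were higher, and Cxcr3 (-2.42) and Cxcl16 (-1.52) lower besides Cx3cr1, Cxcl2 and Cxcl10; with neutrophils added the counts were 7 and 7. Of 17 C-type lectin and Siglec genes 5 rose and 7 fell: Clec7a, which encodes the beta-glucan receptor Dectin-1, rose by 5.13 (4.2e-05) and Clec10a, a close paralog of Mgl2, by 4.70 (0.00169), while Clec4n fell by 2.87 (0.000919), Clec4e fell by 1.88 (0.0031) and Siglece fell by 2.17 (0.0127); in aN+IL-4 the counts were 4 and 6.

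Some genes of other granulocytes were read in libraries that met neutrophils: Prg2 stood at 23.6 in aN and 18.9 and 15.3 in aN+IL-4, against at most 3.51 in the other 4 libraries, while Prss34 stood at 0.907 in aN and 8.40 and 2.18 in aN+IL-4 and Mcpt8 at 0 in aN and 3.15 and 4.37 in aN+IL-4, both at 0 in the libraries without neutrophils. F7, a coagulation factor gene, stood at 8.18 and 10.6 untreated, 193 and 358 in IL-4, 23.6 in aN and 431 and 906 in aN+IL-4. Ms4a4c stood at 249 in aN and 36.8 and 33.8 in aN+IL-4, against 49.1 and 109 untreated and 165 and 115 in IL-4.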
